A study of Mus musculus with 12 samples.

How the data were processed

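ATAC-seq, which maps open chromatin by where a transposase inserts adapters into genomic DNA, was run on mouse granulocyte-monocyte progenitors that carry a fusion of the estrogen receptor with the leukaemia protein HOXA9. The cells came from C57BL6 bone marrow. The 12 libraries form 6 groups of 2 biological replicates. Day0 was sampled untreated at the start. The other groups were sampled on day 2 after DMSO alone (Vehicle), 200 nM GSK-LSD1, an inhibitor of the histone demethylase LSD1 (LSD1i), 5 uM of the purine analogue mercaptopurine (6MP), 5 uM of the fatty acid synthase inhibitor cerulenin (CER), or all 3 drugs at these doses (Combo).

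Per the submitters' processing notes, the tools were Trimmomatic 0.38, Bowtie2, SAMtools 1.9, Picard 2.18.26, MACS2 2.1.2 and DiffBind on the mm10 build; their settings and order are not stated. For each library the authors deposited a list of called peaks with a whole-number score, the fold ratio of the summit over its local background, and the -log10 of the p-value and of the q-value. All listed q-values were 0.01 or less. The authors also deposited 5 annotated comparison tables, Vehicle against Day0 and each drug group against Vehicle, whose levels and folds are log2 of normalised reads with the scaling not stated. Each deposited table gives the p-value and FDR of every listed region, and no listed FDR was above 0.05, so regions past that threshold are what the tables hold. From the ranks of these p-values and FDRs, the authors' tests covered between 39858 and 53239 regions per comparison. A region with a positive fold in the deposited table is called opened and one with a negative fold closed. Every one of the listed regions overlapped the union of the called peaks.

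Summits of one peak were merged, and peaks of all libraries were joined into 73147 union regions, of which 63035 were called in at least 2 libraries and 33367 in all 12. Genes were named as annotated in the authors' deposited table or, for union regions, by the nearest end of 21887 protein-coding genes of the RefSeq annotation of the same mouse assembly. All 383 genes of the preset lists matched that annotation. Read totals are not in the files. Coverage was therefore recovered from the peak lists, by solving the fold ratio and the Poisson p-value of each summit for its fragment pileup and its background. The pileup came out whole, within 0.001 on the -log10 scale, at 100% of summits in every library. Simulated summits, 20000 drawn once and not per library, were recovered exactly. They were made with the formula that was solved, so they check the solution and not the formula. The smallest background of each library, 2.44 to 4.55 fragments per position, was taken as its depth, and log2 of pileup over it is called summit signal. The signal was centred on each library's median over the regions called in all 12 libraries. Scaling by depth leaves this centring out, and centring by intensity removes a trend with mean signal instead. Pileups ranged upward from 10 to 14 fragments at the smallest summits, with medians of 50 to 75, and counting error of this size limits the precision at weak regions.

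The comparisons, the tests on the deposited tables and peak lists, the gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. The recovery of the signal and every test on it were added after seeing the data. Likeness of replicates was tested on the Jaccard index, base pairs covered by both over either, with an exact one-sided permutation over all 10395 matchings of the libraries into pairs. With 2 libraries against 2, an exact two-sided test cannot give a p below 0.333. Regions were therefore compared with limma 3.58.1 in R 4.3.3, with a mean-dependent prior variance estimated over all 12 libraries, on regions called in all 4 libraries of a comparison, and adjusted by Benjamini-Hochberg at 0.05. This leaves out regions that gained or lost a called peak altogether. On 4 simulations of 33367 regions each, limma recovered 59% of changes of log2 1 and 99.5% of changes of log2 2, and 34 of 668 calls were false (5.09%). The simulated noise between libraries was independent, with the same SD (0.212) for all regions and libraries. Differences in enrichment between libraries were not simulated, so these rates need not hold for the real ones. Promoter shares, with promoters as annotated in the authors' deposited table, and the direction of gene lists were compared with Fisher's exact test, two-sided. This test counts regions or genes, not libraries, so its p describes the lists. For libraries outside a comparison, the share of its opened regions holding a called peak minus the share of its closed regions was compared between the libraries of one group and the other 6, by an exact one-sided permutation over 28 splits, in a family of 10 tests. The summit signal was also correlated with the authors' fold for each of the 2970 choices of 2 test and 2 control libraries.

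There were 20 preset lists: primary granule, mature neutrophil, monocyte and macrophage, myeloid surface proteins, progenitor and self-renewal, LSD1-CoREST-GFI1 complex, myeloid transcription factors, purine metabolism, fatty acid and sterol metabolism, p53 targets, integrated stress response, cell cycle and interferon response, and markers of erythroid, megakaryocyte, mast cell with basophil and eosinophil, B, T and NK, dendritic, and stromal and endothelial cells. Direction was tested on the region with the smallest FDR per gene (70 tests). Enrichment was tested against 100000 random lists matched on the number of regions per gene, two-sided, over 15716 genes (160 tests). In a check on simulated lists, 1.25% of null lists fell below 0.05 and 100% of planted ones were recovered. The lists were also tested on the summit signal with camera of limma, with a preset correlation of 0.01 and with an estimated one. Genes named are the 10 opened and the 10 closed regions of largest fold per deposited table that hold a called peak in both libraries of the open group, at most 4 genes per list by smallest FDR, and a fixed set of genes named always. Alternatives were a stricter FDR of 0.01, an absolute log2 fold of 1 or more, other overlaps, promoter definitions and list tests, other scalings, the 4 libraries of a comparison alone, replicate number or the suffix letter of library names as a block, and leaving out each library. A motif search was not run, since genome sequence was not used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.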

Results

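The series addresses how an LSD1 inhibitor and the metabolic inhibitors mercaptopurine and cerulenin, singly or together, change open chromatin in myeloid progenitors whose differentiation HOXA9 blocks. Peak lists held between 42651 and 56398 peaks per library. Group means were 48776 ± 6122 (SD, n = 2) peaks for Day0, 52780 ± 1498 for Vehicle, 53566 ± 4006 for LSD1i, 44678 ± 2169 for 6MP, 46600 ± 5585 for CER and 55672 ± 58.7 for Combo, each with n = 2. Replicates were not closer in peak number than other pairings of the libraries (exact permutation p = 0.164 over 10395 matchings). Median summit signal at the regions shared by all libraries was 28.3 to 42.7 times background in 10 libraries, 23.0 times in CER replicate 2 and 16.9 times in 6MP replicate 1.

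Replicates of a group shared more of their open chromatin than libraries of different groups. The mean Jaccard index was 0.730 within groups and 0.703 between them, and 144 of 10395 matchings gave pairs as alike (exact one-sided permutation p = 0.0139). The nearest library was the own replicate for 4 of 12 libraries, both Combo libraries, LSD1i replicate 1 and Vehicle replicate 2. The difference between these means was 0.0267, and 0.0233, 0.0222, 0.0191 and 0.0182 without LSD1i replicate 1, LSD1i replicate 2, Combo replicate 1 and Combo replicate 2. The exact p was 0.0572 without LSD1i replicate 1, 0.0509 without LSD1i replicate 2, 0.0696 without Combo replicate 1 and 0.0863 without Combo replicate 2.

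**Figure D1:**
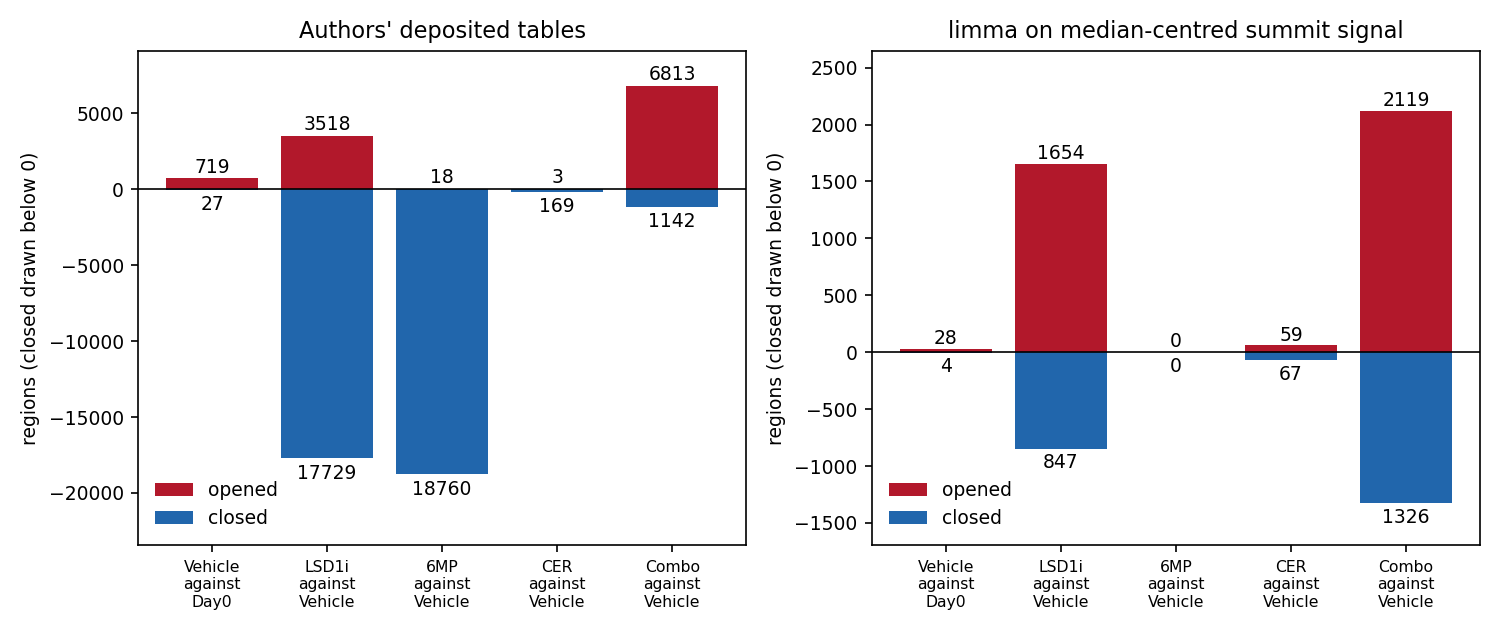
Regions opened (above 0) and closed (drawn below 0) in each comparison; the vertical axes give numbers of regions and have different scales. In the left panel, the authors' deposited tables list 17729 regions closed for LSD1i and 18760 for 6MP; in the right panel, limma on the median-centred summit signal called 847 and 0.

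The first comparison asks what 2 days in culture with DMSO changed. Both Day0 libraries, and no others, carry the name suffix P, so time and whatever that letter stands for cannot be told apart. The authors' deposited table for Vehicle against Day0 listed 719 opened regions, with a median log2 fold of +0.58, and 27 closed ones, with a median of -0.67. Its opened regions lay near Dock4 (+1.51), a guanine nucleotide exchange factor, near Tnfsf18 (+1.28), a ligand of the TNF family, and in intron 2 of Bcr (+1.19, chromosome 10, 75125371 to 75126103), in the words of the authors' deposited table. Smaller gains in the authors' deposited table were at Jun (+0.32) and Fos (+0.28), which encode AP-1 proteins, and at the progenitor genes Erg (+0.49), Cdk6 (+0.65) and Hlf (+1.08). Among closed regions the authors' deposited table held the promoter of Ms4a3 (-0.74), a gene of granulocyte-monocyte progenitors, and a region of Abcb10 (-0.79), a mitochondrial transporter. On the summit signal, the Bcr region rose by 1.15 ± 0.22 (SE, n = 2 per group; limma adjusted p = 0.0237) and the Tnfsf18 region by 1.19 ± 0.24 (adjusted p = 0.0454). None of the 20 lists passed the direction or the enrichment test in this comparison. The nearest were the primary granule list, with 0 genes opened and 1 closed (Fisher's exact adjusted p = 0.512 over 70 tests), and the progenitor list, with 6 of 25 genes holding an opened region against 3.24 expected from random lists.

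Within this comparison limma called 28 opened and 4 closed of 39425 regions (4420 at an unadjusted p under 0.05), and 23 of the 28 were also opened in the authors' deposited table. The calls numbered 7 without Day0 replicate 1, 0 without Day0 replicate 2, 1 without Vehicle replicate 2 and 1191 without Vehicle replicate 1, and scaling by depth gave 1 opened and 0 closed. The majority turned to closed without Vehicle replicate 1 (490 opened and 701 closed) and with the suffix of the library names as a block (613 and 801, or 1414 in all). Promoters made up 36.9% of opened and 55.6% of closed regions in the authors' deposited table (Fisher's exact p = 0.0668).

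The LSD1i comparison asks what the inhibitor alone changed. Among the strongest gains in the authors' deposited table, which reached +4.49, were those at C1qtnf3 (+4.26), Dnah7a (+4.05), Cib4 (+3.91) and Cav3 (+3.83). Intron 2 of Cd83, which encodes a surface protein of mature dendritic cells, stood at +3.54 (FDR 2.09e-60, chromosome 13, 43788659 to 43789488). On the summit signal, the promoter of Mmp8, the neutrophil collagenase (chromosome 9, 7556427 to 7558962), rose by 1.43 ± 0.15 (SE, n = 2 per group; limma adjusted p = 3.85e-07). A region upstream of Cd44, a hyaluronan receptor (chromosome 2, 102967484 to 102968831), rose by 1.47 ± 0.16 (adjusted p = 3.22e-07). Regions of Fpr1, a formyl peptide receptor, of the macrophage scavenger receptor Msr1 and of Tlr2 rose by 1.25 ± 0.28, 0.96 ± 0.28 and 0.60 ± 0.15 (adjusted p = 0.00541, 0.0352 and 0.0158). Closing past the same test reached Cdk6, a cell cycle kinase (-0.85 ± 0.20, limma adjusted p = 0.00857), and the promoters of the progenitor factors Gata2 (-0.48 ± 0.14, 0.0407; chromosome 6, 88202445 to 88204832) and Runx1 (-0.56 ± 0.15, 0.0184). It also reached Chac1, a gene of the integrated stress response (-0.77 ± 0.15, limma adjusted p = 0.00139), and Lgals3, which encodes a galectin (-0.65 ± 0.18, 0.03). These closed genes do not stand for their lists, where limma called more regions opened than closed. The calls were 6 opened and 4 closed of 196 progenitor and self-renewal regions, and 10 and 5 of 184 myeloid transcription factor regions. They were 6 and 2 of 85 for the integrated stress response, and 4 and 2 of 101 for monocyte and macrophage.

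The mature neutrophil list differed from the other genes in some tests after LSD1 inhibition. Among its genes with a region in the authors' deposited table, 6 opened and 2 closed, while 16.7% of all other genes opened (Fisher's exact adjusted p = 0.0318). A closed region in the authors' deposited table was found at 3 of 22 neutrophil genes, against 13.5 expected from matched random lists (adjusted p = 0.0016), and at 3 of 14 dendritic cell genes, against 9.42 (adjusted p = 0.0208). The random lists were matched on regions per gene, not on signal or promoter share. Closed regions had more reads than opened ones (mean log2 10.1 against 7.68), so a depletion of weaker genes as such is not set aside. Dendritic cell genes were depleted alike, at 3 of 14, in the authors' deposited table for 6MP, which did not follow its labelled libraries. Purine metabolism lay on the other side, with 27 of 29 genes holding a closed region against 18.7 (adjusted p = 0.0208), such as Impdh1 (-0.46) and Ppat (-0.33) in the authors' deposited table. The summit signal at these regions was -0.08 ± 0.19 for Impdh1 and -0.11 ± 0.28 for Ppat (SE, n = 2 per group; limma adjusted p = 0.836 and 0.842). The neutrophil direction did not pass when every region was counted (adjusted p = 0.057), among promoters (0.154) or at an FDR of 0.01 (0.424), and purine metabolism did not at an FDR of 0.01 (0.105). On the summit signal, limma called 3 opened and 0 closed of 40 neutrophil regions, 5 and 0 of 42 dendritic cell regions and 1 and 2 of 79 purine regions. Adjusted over the list alone, these became 3 and 1, 9 and 0, and 0 and 2. No list passed camera, where the lowest adjusted p over all comparisons was 0.0523 with the preset correlation and 0.882 with an estimated correlation.

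The remaining lists did not pass the direction test for LSD1i on the best region per gene. With every region counted, markers of dendritic cells, another cell type, passed it with 8 opened and 2 closed in the authors' deposited table (Fisher's exact adjusted p = 0.00116). By the authors' deposited table, opened and closed genes numbered 1 and 7 for primary granules, 4 and 7 for monocyte and macrophage, 3 and 3 for surface proteins, 1 and 14 for progenitor and self-renewal, 2 and 7 for the LSD1-CoREST-GFI1 complex and 2 and 20 for myeloid transcription factors. The same authors' deposited table gave 0 and 23 for purine metabolism, 0 and 24 for fatty acid and sterol metabolism, 1 and 17 for p53 targets, 1 and 17 for the integrated stress response, 1 and 22 for the cell cycle and 1 and 14 for interferon response. On the centred summit signal this balance did not hold for several lists. Limma called 7 opened and 1 closed of 33 regions of the LSD1-CoREST-GFI1 complex, and 4 and 3 of 67 p53 target regions. It called 2 and 0 of 72 cell cycle regions, 1 and 0 of 95 fatty acid and sterol regions, and 0 and 1 of 37 interferon response regions. For markers of other cell types the authors' deposited table gave 2 and 8 (erythroid), 0 and 6 (megakaryocyte), 2 and 4 (mast cell, basophil and eosinophil), 2 and 5 (B cell), 3 and 4 (T and NK cell), 4 and 2 (dendritic cell) and 0 and 4 (stromal and endothelial). Regions of T and NK cell markers went both ways after LSD1i, with 2 opened and 2 closed of 28 by limma, and 3 and 5 adjusted over the list alone. Lymphoid and dendritic markers among the regions opened were Zap70, a T cell kinase, at 1.80 ± 0.26 (SE, n = 2 per group; limma adjusted p = 5.17e-05), the dendritic cell factor Zbtb46 at 1.32 ± 0.28 (0.00357) and Tcf4 at 0.90 ± 0.19 (0.00262). Kdm1a, which encodes LSD1 itself, had a closed region in the authors' deposited table (-1.04, FDR 3.44e-07) that did not pass limma (-0.42 ± 0.25, adjusted p = 0.356). Genes of primary granule proteins were likewise closed in the authors' deposited table, Prtn3 by -1.03, Mpo by -0.69 and Elane by -0.55, and the Mpo and Elane regions did not pass limma (adjusted p = 0.922 and 0.0759), while that of Prtn3 was not tested. Limma called 0 opened and 0 closed of 24 primary granule regions, also adjusted over the list alone. Regions of further myeloid and metabolic regulators were closed in the authors' deposited table for LSD1i, Cebpe (-0.68) and Cebpa (-0.30), factors of granulocyte development, Spi1 (-0.32), Irf8 (-0.77), Myc (-0.31), Kit (-0.21), Fasn (-0.39) and Hprt (-0.39). Except at Irf8, which was not tested, limma adjusted p at these regions was between 0.277 and 0.999. Kit also had 2 opened regions in the authors' deposited table, Gfi1b 2 and Gfi1 1 (+0.36 and +0.48 at the best region of each). Lyz2 and Cd34 had none for LSD1i and 1 opened each in the authors' deposited table for Combo. Meis1, Hoxa9, Itgam and Flt3 had no region in any of the 5 deposited tables.

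**Figure D2:**
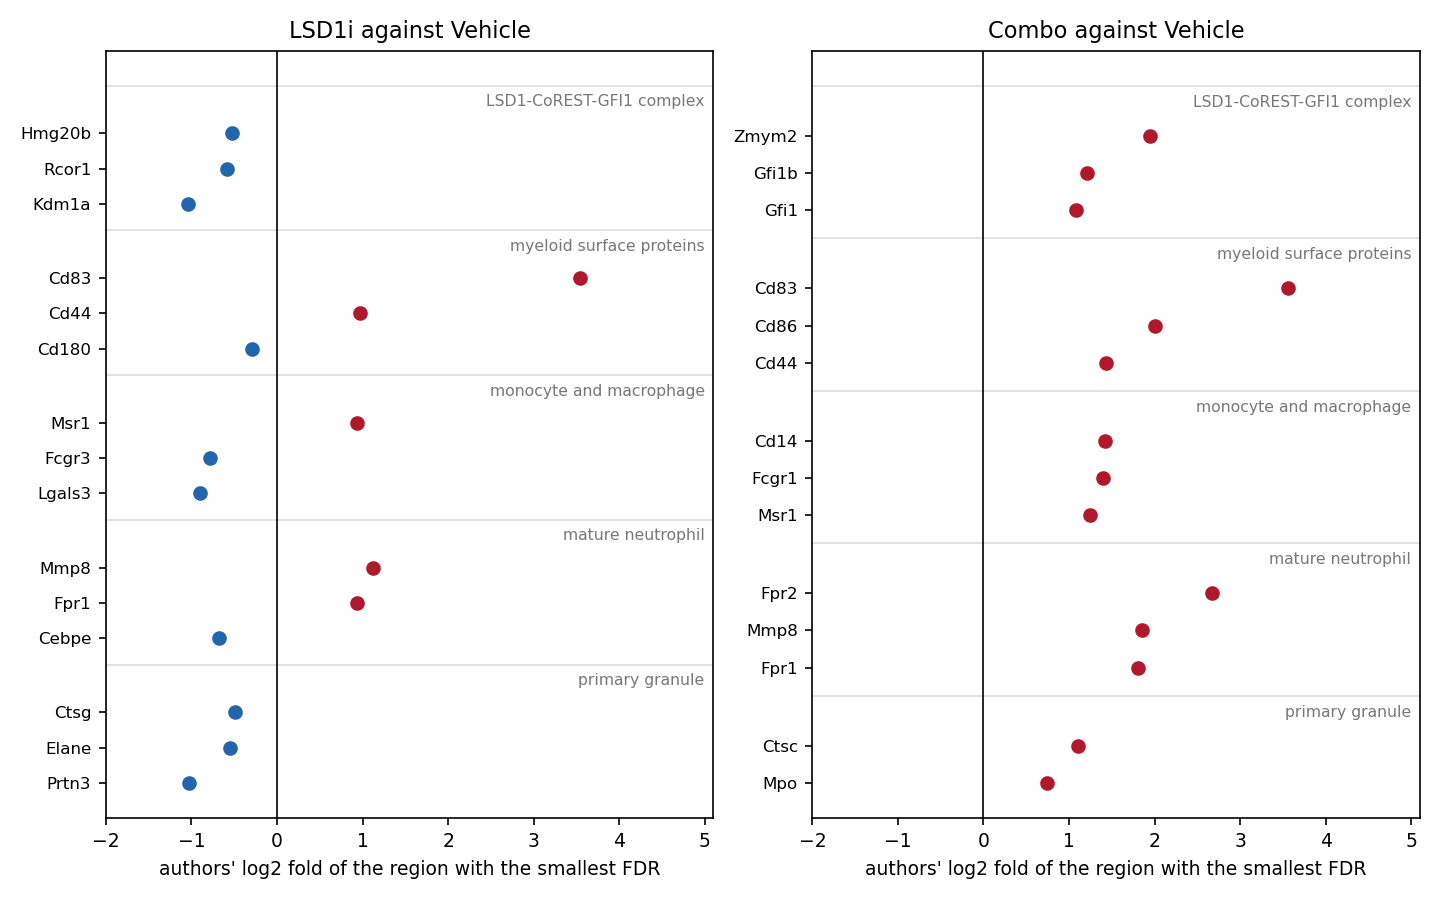
Authors' log2 fold (horizontal axis) of the region with the smallest FDR, for up to 3 genes of each named list by smallest FDR (vertical axis), after LSD1i (left) and Combo (right) against Vehicle; each point is 1 region of the authors' deposited table. Cd83 lies at +3.54 for LSD1i and +3.56 for Combo; all points drawn for Combo lie above 0, and the primary granule genes drawn for LSD1i lie below 0.

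Opened and closed regions of the LSD1i comparison differed in position. The authors' deposited table listed 3518 opened regions, 21.3% of them at promoters and 39.2% intergenic, and 17729 closed regions, 62.7% at promoters. This difference exceeded what Fisher's exact test can express as a p, which was returned as 0. Regions are not independent replicates, so that p describes the lists and not the spread between libraries. The closed regions were many and small, with a median fold of -0.48 in the authors' deposited table against +0.83 for opened ones, and 623 of them reached an absolute log2 fold of 1. Limma called 1654 opened and 847 closed of 41322 regions, so that 66.1% of calls were opened. Scaling by depth gave 169 and 31, or 84.5% opened, and the 4 libraries with a replicate block 3303 and 2716, or 54.9%. Relative to depth, the median of all regions shifted by -0.23 in LSD1i against Vehicle, and the limma values are relative to that shift. At the 16319 closed regions called in all 4 libraries, the median summit signal difference was -0.38 scaled by depth and -0.14 centred. Of the limma calls, 1321 opened and 835 closed ones were listed with the same direction in the authors' deposited table. Without Vehicle replicate 1, LSD1i replicate 1 or LSD1i replicate 2, limma called 1127, 708 and 655 regions in place of 2501.

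The 6MP comparison asks what a purine analogue alone changed. The authors' deposited table listed 18760 closed regions, with a median fold of -0.59, and 18 opened ones. Its closed regions held at least 1 region at 26 of 26 cell cycle genes, against 16.7 expected from matched random lists (adjusted p = 0.0016), such as E2f2 (-0.80) and E2f1 (-0.67) in the authors' deposited table, and at 3 of 14 dendritic cell genes, against 9.9 (adjusted p = 0.0096). Purine metabolism had 22 closed genes and 0 opened in the authors' deposited table, with Nt5c2, a nucleotidase that acts on purine nucleotides, at -0.99. On the median-centred summit signal the libraries labelled 6MP did not show these changes. At the E2f2 and E2f1 regions, 6MP minus Vehicle on the summit signal was -0.02 ± 0.18 and -0.08 ± 0.20 (SE, n = 2 per group), and at the Nt5c2 promoter 0.14 ± 0.27, each with a limma adjusted p of 1. Scaled by depth, all common regions shifted by a median of -0.46 in 6MP, and the listed closed regions by -0.48. This shift differed between the libraries at the closed regions, -1.15 in 6MP replicate 1 and +0.20 in replicate 2.

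Across 17169 regions, which are not independent replicates, the authors' fold in the deposited table for 6MP had a correlation of -0.149 with the summit signal of the libraries labelled 6MP minus Vehicle. This labelled choice ranked 1995 among the 2970 choices of 2 test and 2 control libraries. The highest correlation, 0.777, came from LSD1i replicate 1 and CER replicate 2 against Vehicle replicate 1 and 6MP replicate 2. The names of the first 2 carry no suffix letter, and those of the last 2 carry R. For the other tables the labelled libraries ranked 1 (Vehicle against Day0, 0.886; LSD1i, 0.949; Combo, 0.974) or 2 (CER, 0.890, over 37 regions). All 18 regions that the authors' deposited table lists as opened for 6MP held a called peak in LSD1i replicate 1 and in CER replicate 2, against 16.7% of them in 6MP replicate 1 and 5.56% in 6MP replicate 2. Limma on the labelled libraries called 0 of 37143 regions, with 1883 at an unadjusted p under 0.05. It called 18 without Vehicle replicate 1, 1 without Vehicle replicate 2 and 9 without 6MP replicate 1. Adjusted over the list alone, 1 purine region opened and 1 closed of 71, and 0 of 67 cell cycle regions passed. The 6MP table is therefore given as deposited, and no region in it is described as changed by mercaptopurine. The closed regions of the authors' deposited table for 6MP overlapped 15169 of those closed for LSD1i, 85.6% of these, against 5276 expected, and the folds of both tables had a correlation of 0.818 across 15118 regions, which are not independent replicates. By their labels both tables have the Vehicle libraries as control. In the choice of libraries that gave 0.777, LSD1i replicate 1 was moreover a test library of the 6MP table. This overlap is therefore not shown to be one between 2 separate drugs.

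**Figure D3:**
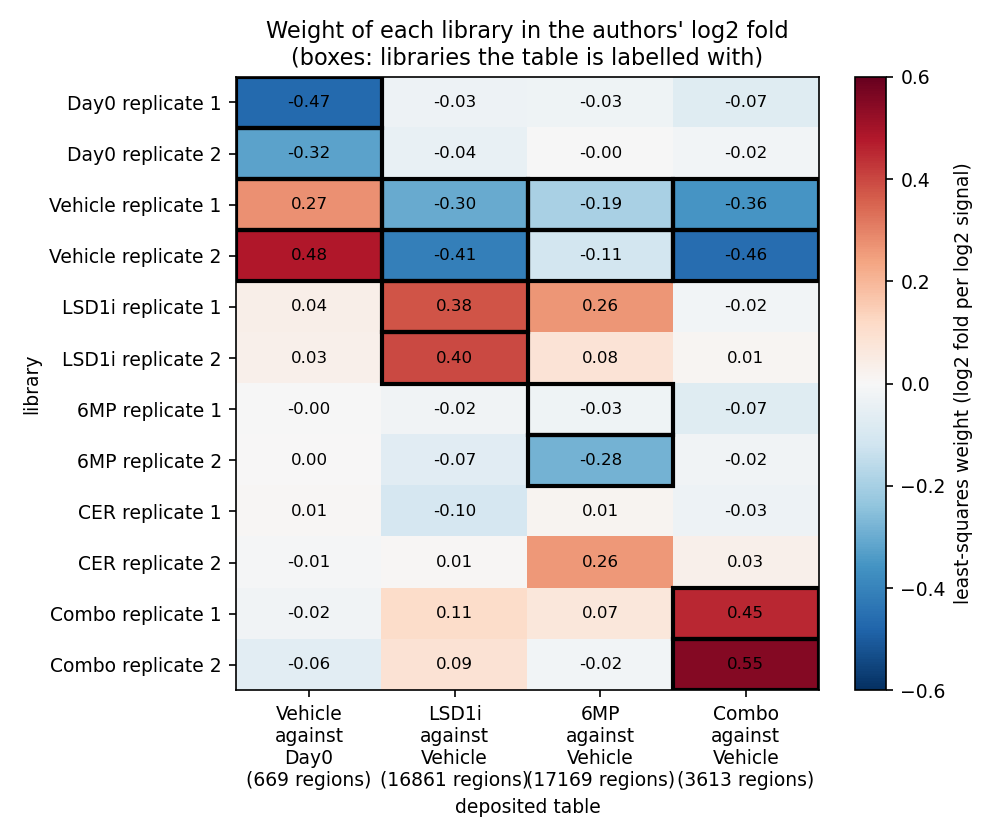
Least-squares weight of the summit signal of each library (rows) in the authors' log2 fold of each deposited table (columns, with the number of regions used); boxes mark the libraries a table is labelled with. In the 6MP column the largest weights are -0.28 (6MP replicate 2), 0.26 (LSD1i replicate 1) and 0.26 (CER replicate 2), so that a 6MP library has a negative weight and the positive ones lie outside the boxes, while in the other columns the largest weights lie in the boxes with the sign of their label.

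The CER comparison asks what cerulenin alone changed. The authors' deposited table listed 169 closed regions, all with an absolute log2 fold of 1 or more and a median of -1.23. These included the promoters of the natural killer receptor gene Klri2 (-1.83, chromosome 6, 129740119 to 129740579) and of Dnaaf5 (-1.76), an assembly factor of dynein arms, and a region of Pde4b (-1.52), a cyclic AMP phosphodiesterase, by the authors' deposited table. The 3 opened regions of the authors' deposited table were intergenic, nearest to Yipf5 (+1.32), Lonrf1 (+1.25) and Gm25042 (+1.11), the last of which lies outside the rule for named genes and was chosen after its value was seen. No fatty acid or sterol gene had a region in the authors' deposited table for CER. Of the lists, only the erythroid membrane gene Epb42 (-1.14) was annotated in the authors' deposited table. No list passed its tests. At an FDR of 0.01, 0 opened and 12 closed regions of the authors' deposited table were left.

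On the summit signal limma called 59 opened and 67 closed of 38409 regions for CER, 46.8% opened, with 4639 at an unadjusted p under 0.05. In the fatty acid and sterol list it called 0 opened and 1 closed of 90 regions, and 1 and 5 adjusted over the list alone. Of the calls, 1 opened and 14 closed were listed in the authors' deposited table. The total of 126 fell to 0 without CER replicate 2, 13 without CER replicate 1 and 3 without Vehicle replicate 2, and was 1208 without Vehicle replicate 1. Scaling by depth gave 0 opened and 1 closed, and centring by intensity 102 and 212, or 32.5% opened. The calls numbered 865 with the suffix of the library names as a block, and 0 from the 4 libraries alone or 1234 with a suffix or replicate block.

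The Combo comparison asks what the 3 drugs changed together. Among the largest gains in the authors' deposited table were those at exon 6 of Ptgfrn (+5.65), C1qtnf3 (+4.63), Slc12a8 (+4.28), a solute carrier, and Cib4 (+4.08). Cd83 stood at +3.56. On the summit signal, the Mmp8 promoter rose by 1.79 ± 0.15 (SE, n = 2 per group; limma adjusted p = 4.32e-09), the Fpr1 region by 1.74 ± 0.28 (9.74e-05) and the promoter of Camp, an antimicrobial peptide of neutrophil granules, by 0.98 ± 0.25 (0.00964). Regions of the Fc receptor gene Fcgr1 and of Irf4 rose by 1.33 ± 0.32 and 1.34 ± 0.27 (adjusted p = 0.00658 and 0.00157). Genes of the repressors that recruit LSD1 also gained signal, Gfi1b by 1.01 ± 0.16 (5.73e-05) and Gfi1 by 0.93 ± 0.20 (0.00276). Closing reached Irf8, a factor of monocyte and dendritic cell development (chromosome 8, 120747377 to 120748244), at -1.08 ± 0.26 (0.007), the AMP deaminase gene Ampd2 at -0.97 ± 0.14 (1.74e-05), Bbc3, a p53 target, at -0.96 ± 0.17 (0.000234), and the promoter of Rnase11 at -2.21 ± 0.24 (1.85e-07).

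Neutrophil genes held opened regions in the Combo table more often than matched random genes, 11 of 22 against 4.35 expected (adjusted p = 0.0208). In the authors' deposited table, 11 neutrophil genes opened and 0 closed, with 12 and 2 for monocyte and macrophage, 6 and 0 for surface proteins, 5 and 3 for progenitor and self-renewal and 3 and 0 for the LSD1-CoREST-GFI1 complex. None of these differed from the 83.5% opened among other genes of the authors' deposited table (Fisher's exact adjusted p of 0.834 or more). For markers of other cell types the authors' deposited table for Combo gave 7 and 0 (mast cell, basophil and eosinophil), 5 and 0 (T and NK cell), 3 and 0 (dendritic cell), 3 and 0 (B cell), 2 and 0 (stromal and endothelial), 2 and 1 (erythroid) and 1 and 1 (megakaryocyte). None of these differed from the other genes either (Fisher's exact adjusted p = 1). The mast cell genes Mitf and Cpa3 rose by 0.84 ± 0.20 and 0.69 ± 0.15 (SE, n = 2 per group; limma adjusted p = 0.00526 and 0.0037), and Itga2b of megakaryocytes stood at -0.74 ± 0.17 (0.00453). The neutrophil enrichment did not pass unmatched (0.112), at an FDR of 0.01 (0.114) or among promoters (0.18). On the summit signal, limma called 6 opened and 1 closed of 43 neutrophil regions and 8 and 0 of 60 surface protein regions, and 8 and 2 and 11 and 3 adjusted over the list alone.

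The authors' deposited table for Combo listed 6813 opened regions, with a median fold of +0.98, and 1142 closed ones, with a median of -0.78. Promoters made up 21.2% of opened and 30.1% of closed regions in the authors' deposited table (Fisher's exact p = 8.09e-11). Within 1000 bp of a gene start were 11.1% and 14.8% (Fisher's exact p = 0.000473). Both p-values count regions, which are not independent replicates, and describe the lists only. Limma called 2119 opened and 1326 closed of 42677 regions, 61.5% opened, and scaling by depth 1200 and 35, or 97.2% opened. From the 4 libraries alone with the suffix block, most calls were closed (4183 opened and 6065 closed, or 40.8% opened). The median of all regions relative to depth was shifted by +0.12. Of the limma calls, 2057 opened and 535 closed were listed in the authors' deposited table. The 3445 calls became 2109 without Vehicle replicate 1, 1498 without Combo replicate 1 and 1439 without Combo replicate 2.

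Most regions opened by LSD1 inhibition alone were also opened by the combination. The authors' deposited tables shared 2728 opened regions, 77.5% of the 3518 for LSD1i and a smaller part of the 6813 for Combo, against 380 expected by chance overlap. They shared 998 closed regions, 5.63% of those for LSD1i and 87.4% of those for Combo, against 321. CER and Combo shared 56 closed regions of the authors' deposited tables, against 3.06. These comparisons share their Vehicle libraries, which raises any overlap. Libraries that did not enter a comparison give a reading without that sharing. At LSD1i-opened regions a called peak was present at 93.9% and 92.7% in the Combo libraries and at 48.3% to 59.8% in the libraries of Day0, 6MP and CER. The share at opened minus closed regions was -2.92 points in the Combo libraries and -42.4 in the other 6 (exact permutation p = 0.0357, the smallest that 28 splits allow; adjusted p = 0.179), with both Combo libraries above all others. At the regions of the Combo comparison, the LSD1i libraries stood at 15.4 points and the other 6 at -16.4 (exact permutation p = 0.0357, adjusted p = 0.179). For 6MP and CER libraries, and at the regions of Vehicle against Day0, the exact p was 0.143 or more. Of the 719 regions opened in Vehicle against Day0, 399 were listed as closed for LSD1i, 428 for 6MP and 54 for Combo in the authors' deposited tables. Vehicle is the test group of the first comparison and the control of the others, which by itself gives such overlaps, and no test set this aside.

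**Figure D4:**
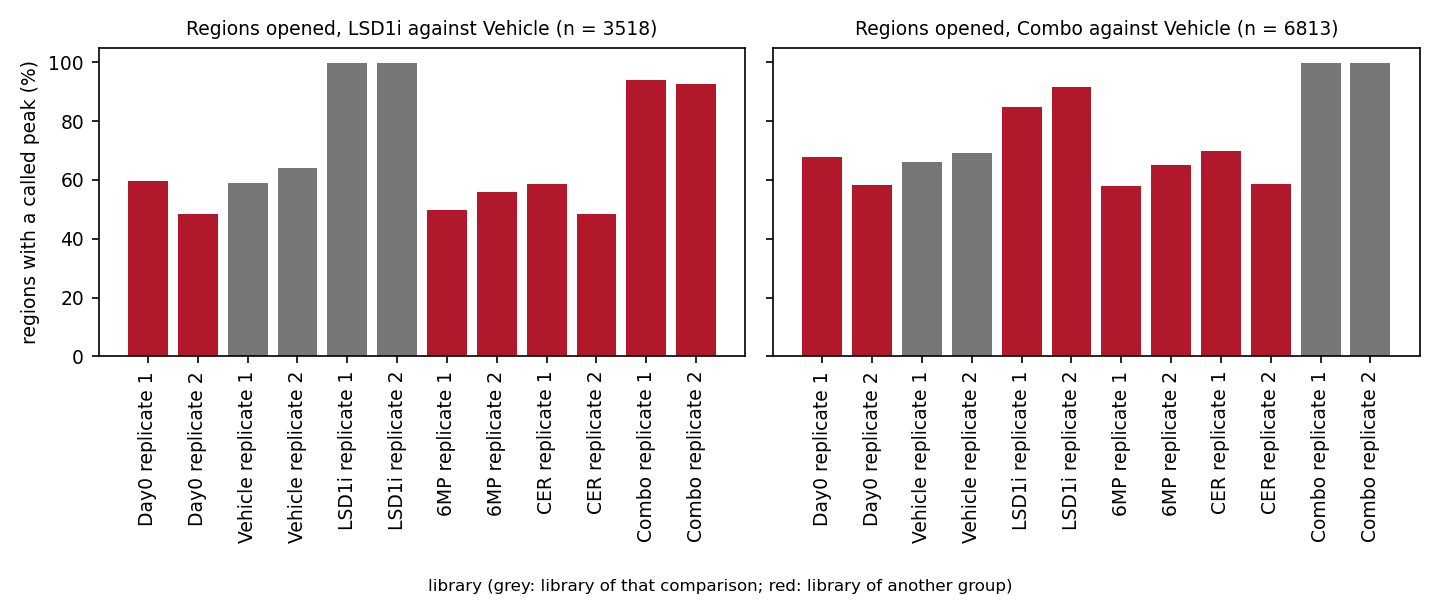
Share of the regions opened in the authors' deposited tables for LSD1i (left) and Combo (right) that hold a called peak (vertical axis, percent) in each of the 12 libraries; grey bars are libraries of the comparison shown, red bars all others. Among red bars, the Combo libraries stand at 93.9% and 92.7% on the left and the LSD1i libraries at 84.7% and 91.6% on the right, above all other red bars.

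At regions opened in both authors' deposited tables, the fold was larger for Combo at 88.6% of 2718 regions, by a median of +0.31. Compared directly, Combo minus LSD1i on the summit signal had a median of -0.05 at these regions, and of +0.32 when scaled by depth. Limma called 39 regions higher and 10 lower in Combo than in LSD1i, of 43669 (4728 at an unadjusted p under 0.05). Regions nearest to Dusp2, a phosphatase of MAP kinases (chromosome 2, 127322471 to 127323974), to Inf2, a formin, and to Lgmn, a lysosomal protease, were higher by 1.63 ± 0.26, 0.99 ± 0.16 and 1.13 ± 0.19 (SE, n = 2 per group; limma adjusted p = 0.0144, 0.0144 and 0.017). The myeloid genes Cd44, Cd93 and Klf6 had distal regions higher by 1.19 ± 0.25, 1.18 ± 0.24 and 0.90 ± 0.19 (adjusted p = 0.0384, 0.0384 and 0.046). None of these named higher regions was among those opened in both tables. The authors' deposited table for LSD1i listed each as closed: Dusp2 -0.9, Inf2 -0.93, Lgmn -0.64, Cd44 -0.51, Cd93 -0.77 and Klf6 -0.47. Some other regions higher in Combo, such as that nearest to Auts2 (+0.79), were listed there as opened. Among the lower regions, that nearest to Gng7, a G protein subunit, stood at -1.21 ± 0.21 (0.0179) and a distal one nearest to Tlr4 at -1.23 ± 0.26 (0.046). These genes were chosen after their values were seen. The calls numbered 0 without LSD1i replicate 1, LSD1i replicate 2 or Combo replicate 2, and 15 without Combo replicate 1. Of the calls 79.6% were higher in Combo, against 138 higher and 0 lower scaled by depth and 117 and 10 centred by intensity. The 4 libraries alone gave 1266 higher and 1023 lower, or 55.3% higher, and 1285 and 986 with a replicate block.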

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

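The tests on the 6MP table and the region counts between Combo and LSD1i were chosen after the results were seen; the tests on promoters and on the share of regions above or below were written before theirs.

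Combo and LSD1i, which share the LSD1 inhibitor, differed at 49 regions by limma, a test of the difference itself between these groups. Both replicates of Combo lay above both of LSD1i at 22.5% of the 2716 regions opened in both deposited tables and called in all 4 libraries, more than the 16.7% chance gives, which is what added drugs moving chromatin beyond LSD1i would need. Both also lay below at 31.1%, so the one-sided bound written beforehand was badly chosen, and whether cerulenin and mercaptopurine add to the inhibitor stays open. Scaled by depth, the share above was 58.3%. Over all 43669 regions called in the 4 libraries, the centred share above was 18.4%, also more than 16.7%. The calls fell to 0 without either LSD1i library or without Combo replicate 2, and to 15 without Combo replicate 1.

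The 18760 regions that the authors' deposited table lists as closed for 6MP may come from other libraries than the 4 it names, since the labelled choice ranked 1995 of 2970 by Pearson correlation and the other 4 tables ranked theirs 1 or 2 (by rank correlation 2076 against 1, 1, 3 and, over the 37 regions of CER, 70). For low enrichment of 6MP replicate 1 under scaling by depth, its signal was asked to follow the authors' fold over the closed regions, and that correlation was -0.26. A loss by one factor predicts no such correlation, so this value cannot exclude it. The depth-scaled shift at these regions was -1.15 in 6MP replicate 1 and +0.20 in replicate 2. For an effect of mercaptopurine on the labelled libraries, positive correlations were also asked for, and the higher of the 2 was -0.048. Both correlations restate that the listed folds do not follow the labelled libraries. Neither excludes low enrichment or a drug effect in those libraries. The same measure was 0.744 and 0.696 for the LSD1i libraries and 0.455 and 0.141 for the CER libraries at their own closed regions. Which libraries or which file is out of place stays open, and no region of that table can be read as a mercaptopurine effect here.

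For the closing of promoter regions listed for LSD1i, the regions compared were those within 1000 bp of either end of a gene. These were 9381 of the 33367 regions called in all 12 libraries, and not the annotated promoters of the authors' deposited table. They shifted by -0.16 relative to other regions, beyond the replicate differences of 5 groups (at most -0.132) but not that of 6MP (0.389). The shift lies outside the range of replicate differences, -0.132 to 0.389, so the bound written against a loss by one factor was met. Replicate order is arbitrary, however, so sizes were compared, and the 6MP difference is larger in size. Since replicates with unequal enrichment can thus differ at such regions, lower enrichment of the LSD1i libraries by one factor is not excluded. Matched on signal, the shift was -0.044 against replicate differences of up to 0.15 in size, so a loss that depends on signal strength stays open too. By pairs of libraries, the matched shift was -0.0955 and -0.144 for LSD1i replicates 1 and 2 against Vehicle replicate 1. Against Vehicle replicate 2 it was 0.0479 and -0.00206. The matched shift thus rested on Vehicle replicate 1, whose name, unlike those of the LSD1i libraries, carries the suffix R. For the inhibitor itself, the matched shift in Combo was -0.021, which met the bound written against it, but that bound was wrong because the replicate spread exceeds even the LSD1i value. These explanations cannot be told apart. The matched shifts are smaller than the largest replicate difference, and the unmatched one is exceeded in size by the 6MP replicates alone.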

How the results depend on the processing

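All alternatives on the summit signal, and the ranks of the labelled libraries, were chosen after seeing the data; the others were fixed beforehand. Of 259 alternatives to 72 results, 166 left the result where it was, 76 moved a count or value, 12 weakened a result, by ending its call or, for the CER libraries, lowering a rank, 1 strengthened one and 4 reversed a sign. The cause was not tested in any case below, except where fewer libraries or a stricter threshold explain it by construction. With 2 libraries per group, and with a lone library assumed to vary like the other groups, depth and replicate number limit all counts. The planned motif search was not run, because no genome sequence was used here.

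The exact permutation p of the likeness of replicates ranged from 0.00366 to 0.0863 when 1 library was left out, and was not past 0.05 without LSD1i replicate 1 (0.0572), LSD1i replicate 2 (0.0509), Combo replicate 1 (0.0696) or Combo replicate 2 (0.0863). With replicate number as a replicate block, the exact permutation p was 0.00972.

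At an FDR of 0.01, the authors' deposited tables held 266 opened and 2 closed regions for Vehicle against Day0, 4 opened for 6MP, 0 opened and 12 closed for CER, and 562 closed for Combo. At an absolute log2 fold of 1, the authors' deposited tables held 47 and 2 for Vehicle against Day0, 1276 and 623 for LSD1i, 806 closed for 6MP, and 3303 and 267 for Combo. Of the 18 regions opened for 6MP in the authors' deposited table, 0 held a called peak in both 6MP libraries, and 1 and 3 when replicate 1 or replicate 2 was left out. At the FDR of 0.01, regions opened in Vehicle against Day0 overlapped 7 opened and 140 closed for LSD1i (36 and 399 before), 138 closed for 6MP (428), and 10 opened and 14 closed for Combo (38 and 54). At that FDR, LSD1i closed regions overlapped 3 closed for CER (67 before), 5 opened for Combo (50) and 475 closed for Combo (998). The 6MP closed regions overlapped 2 closed for CER (47 before), 11 opened for Combo (169) and 321 closed for Combo (785), and CER and Combo shared 2 closed (56).

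The signs that reversed were all of peak calls at the regions of Vehicle against Day0, none of which passed its test. The 6MP libraries went from 4.05 points to -4.64 with equal numbers of top peaks and to -0.809 without 6MP replicate 1 (8.91 without replicate 2). The CER libraries went from -2.37 to 5.64 without CER replicate 1 (-10.4 without replicate 2), and the Combo libraries from -8.20 to 3.29 with equal numbers of top peaks.

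The number of lists past the direction test fell from 1 to 0 among promoters and at an FDR of 0.01. With every region counted it stayed at 1, but dendritic cell markers passed in place of the mature neutrophil list. The neutrophil list after LSD1i had Fisher's exact adjusted p of 0.057, 0.154 and 0.424 with every region counted, among promoters and at that FDR. Enriched lists numbered 10 in place of 6 with unmatched genes and also 10 among promoters. Purine metabolism in LSD1i closed regions had 0.105 at an FDR of 0.01, and mature neutrophil genes in Combo opened regions had 0.112 unmatched, 0.114 at an FDR of 0.01 and 0.18 among promoters. Within 1000 bp of a gene start, the promoter share of opened minus closed regions was -28.2 points for 6MP in place of -24.9, with an adjusted p of 0.0302 in place of 0.077 (unadjusted 0.0181 and 0.0462). It shrank from -18.7 to -3.62 points for Vehicle against Day0, from -24.9 to -13.0 for CER and from -8.96 to -3.69 for Combo, and was -43.6 in place of -41.3 for LSD1i. The labelled libraries of the CER table ranked 70 by rank correlation in place of 2.

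Limma calls for Vehicle against Day0 numbered 32, 1 scaled by depth, 1414 with the name suffix as a block, 0 from the 4 libraries alone, 1074 from these with a replicate block, and 0 to 1191 with 1 library left out. For LSD1i they numbered 2501, 200 scaled by depth, 6019 from the 4 libraries with a replicate block, and 655 to 3364 with 1 left out. For 6MP they numbered 0, 1 scaled by depth, 26 with the suffix block and 0 to 18 with 1 left out. For CER they numbered 126, 1 scaled by depth, 314 centred by intensity, 865 with the suffix block, 0 from the 4 libraries, 1234 from these with a suffix or a replicate block, and 0 to 1208 with 1 left out. For Combo they numbered 3445, 1235 scaled by depth, 10248 from the 4 libraries with the suffix block, and 1439 to 2756 with 1 left out. Between Combo and LSD1i they numbered 49, 138 scaled by depth, 127 centred by intensity, 92 with a replicate block, 222 with the suffix block, 2289 from the 4 libraries, 2271 from these with a replicate block, and 0 to 15 with 1 left out. Combo minus LSD1i at regions opened in both tables was -0.05, and +0.32 scaled by depth.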

Other observations

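All tests on the summit signal in this part were chosen after seeing the data. With the 3 drugs together, single regions of metabolic and stress genes passed limma in both directions. Elovl6, a fatty acid elongase, rose by 0.72 ± 0.16 (SE, n = 2 per group; limma adjusted p = 0.00418), Nt5e, an ecto-nucleotidase, by 0.88 ± 0.24 (0.0184), and Adk, adenosine kinase, by 0.82 ± 0.25 (0.0424). Psat1, an enzyme of serine synthesis, and the amino acid transporter gene Slc7a5 rose by 0.78 ± 0.17 and 0.74 ± 0.21 (limma adjusted p = 0.00378 and 0.0283), while Cebpb stood at -0.68 ± 0.15 (0.0028). In the authors' deposited table for Combo, opened and closed genes numbered 3 and 3 for purine metabolism, 3 and 1 for fatty acid and sterol metabolism, and 3 and 1 for the integrated stress response, and no list passed. Limma called 3 opened and 6 closed of 81 purine regions in Combo, and 6 and 6 adjusted over the list alone.

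Of megakaryocyte regions, limma called 0 opened and 5 closed of 37 in Combo, and 0 and 8 adjusted over the list alone. After LSD1i it called 0 and 2 of 35, and 1 and 4 adjusted over the list alone. In the authors' deposited table for Combo, 1 gene of this list opened and 1 closed. The progenitor and self-renewal list had 12 opened and 10 closed of 204 regions in Combo, and 14 and 10 adjusted over the list alone, and 6 and 4 of 196 after LSD1i. Myeloid transcription factors had 16 and 10 of 192 regions in Combo and 10 and 5 of 184 after LSD1i, and 23 and 15 and 13 and 6 adjusted over the list alone.

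The drug groups share their Vehicle libraries, which by itself correlates their changes. Simulated groups with no change had a correlation of 0.501 (0.484 to 0.517) across 33367 regions, which are not independent replicates. The simulation gave a region the same spread in every library, which sets that correlation near 0.5. LSD1i and Combo reached 0.746, and 0.383 and 0.556 when each was compared with a different Vehicle library, while the other pairs of drug groups lay between 0.0661 and 0.42. These other pairs lay below the whole simulated range, so the simulation does not describe these libraries and is no test of 0.746. The covariance of LSD1i and Combo exceeded the simulated one by 0.0717, and for the other pairs this difference was between -0.0166 and 0.0101.

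Names of some libraries carry a suffix letter whose meaning the labels do not give. It is P in both Day0 libraries, and R in Vehicle replicate 1, 6MP replicate 2, CER replicate 1 and Combo replicate 2. The suffix block set R against all other libraries, so it cannot adjust for P, which Day0 alone carries. Within the 4 groups that hold libraries with and without R, the mean correlation of their differences was 0.18. This was the highest of 8 assignments (exact permutation p = 0.125, highest other 0.0849). Libraries with the same replicate number were not more alike than others, with a Jaccard difference of -0.00109 (15 of 32 relabellings as large, exact permutation p = 0.469). Regions within 1000 bp of either end of a gene shifted by 0.116 relative to other regions in CER against Vehicle, and by 0.112 matched on signal. The Vehicle libraries of this comparison differed from each other by more, -0.132 and -0.15 matched (replicate 2 minus 1). The CER shift is therefore not beyond the spread of replicates.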
